A study of Homo sapiens with 8 samples.

How the data were processed

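RNA sequencing was available for 8 libraries from 2 human B-cell lines, MEC1 and GM12878, each at 0, 2, 6 and 24 h after addition of the splicing modulator SD6 at 125 nM. Each line and time had 1 library. RNA was extracted with Qiazol and libraries were made with a KAPA stranded mRNA kit, per the labels' protocols. Reads were aligned with TopHat2 2.1.1 to the human genome build hg19 and summarised with Cuffdiff, per the submitters' processing notes, which give no Cuffdiff version, gene annotation, filter or library scaling. The deposited values are in FPKM, fragments per kilobase of transcript scaled to library size, by a method that is not stated. This unit is not written in the file and was read from the values: they are not whole, the columns sum to between 275582 and 354138, and the low values of a gene step by a multiple that depends on the gene. With 1 library per column, no replicates had been pooled.

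The table held 23284 genes or transcripts, named by symbol and without coordinates, and all 8 columns were matched to a library, leaving 0 unmatched. Values were 0 in every library for 4550 symbols. 28 names were plain numbers and 2 were duplicated. No mitochondrially encoded gene was listed. Intron numbers, gene types and transcript lengths came from GENCODE release 29, matched on symbol and older symbol. That release is on another genome build than the reads, so no coordinates were carried over to the reads. Positions within the release served only to place small RNAs inside or outside other genes on the same strand, and in their introns. An exon structure was found for 96.8% of the 10925 genes tested. Small RNAs, taken by symbol, made up 1606 entries, of which 139 had a mean of at least 1 FPKM. They cover small nucleolar, Cajal body, small nuclear and micro RNAs, and any Y, RN7, vault, RMRP, RPPH and TERC RNAs in the table.

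The table gives no read totals. In 4460 entries the values came within 0.01 of whole multiples of 1 fragment, and 440 of these genes with a single annotated transcript of at least 2000 bases gave an estimated depth per library. It was 16.7, 18.9, 20.1 and 29.8 megafragments (M) for GM12878 at 0, 2, 6 and 24 h, and 26.9, 20.6, 20.4 and 20.8 M for MEC1. These estimates rest on annotated lengths and on the assumption that values were scaled to the mapped fragments of each library. They did not enter the tests of genes and lists, and served for precision, for the change in depth between libraries and for fragments of small RNAs relative to depth. Intervals on fragments are 95% intervals and cover counting error only.

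The choices below were made before the data were examined unless stated otherwise. Log2 changes were taken on log2(FPKM + 1), which understates the change of low genes. Within a line, each time was compared with that line's 0 h library over genes with a mean of at least 1 FPKM in the line. These comparisons have no replicates, so they have no p-value, and counts are of genes changed at least 2-fold. The change shared by both lines was tested with limma 3.58.1 in R 4.3.3, with the intensity trend, in an additive model of cell line and time over the 8 libraries. It leaves 3 residual degrees of freedom, with 3.40 prior degrees of freedom added by the moderation. A response that differs between the lines counts as residual spread in this model. The same model gave the difference between the lines. P-values are two-sided and adjusted by the Benjamini-Hochberg method over genes for each coefficient, with a threshold of 0.05. Such an adjusted p describes agreement between 2 cell lines with 1 culture each, not between repeated cultures. The planned count test was not run because the file holds no counts.

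Of 27 gene lists written down beforehand, the 22 with at least 5 members at a mean of 1 FPKM or more were tested with camera (limma) at a preset correlation of 0.01 between genes and again with an estimated correlation, adjusted over lists within each coefficient. In addition, each list's median in each line and time was placed among the medians of 10000 random lists of the same size matched on mean value, as a description of these libraries. Protein-coding genes without an annotated intron were placed among random lists of protein-coding genes, with or without introns, in the same way. On simulated data made from these libraries, with 67, 67 and 66 of 10779 genes changed at 24 h against 0 h, the model recovered 1.49% at a log2 size of 0.5, 56.7% at 1 and 93.9% at 2. It made 9 false calls at 24 h and 0 at 2 h. A list shifted on purpose had an adjusted p of 4.92e-14, and 0 unshifted lists were called. The simulated genes varied independently of each other, and most were unchanged. False calls among correlated genes, or under a shift of most genes, were therefore not tested. Smaller calculations and figures used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

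Named genes followed a rule over genes with a mean of at least 5 FPKM, leaving out immunoglobulin variable segments and sex-linked genes that mark a person. The rule took, in each direction, 5 genes at 2 h and 10 at 6 h and 24 h that passed the test and moved the same way in both lines, ranked by the smaller of the 2 changes. It also took 3 genes per line and direction at 24 h with a log2 change of at least 1 in that line and under 0.3 in the other, the 8 genes with the largest difference between the lines in each direction, the 2 highest and 2 lowest members of each list at 24 h, and 17 genes chosen beforehand. Because small RNAs took many of these places on very few fragments, the ranking was repeated without them. Genes that entered only this repeated ranking were chosen after the values were seen.

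Alternatives were a pseudocount of 0.1 or 5, a minimum mean of 5 FPKM or no filter, each library rescaled so that its median log ratio was 0 over genes with a mean of at least 5, limma without the intensity trend, only the 4 libraries of 0 h and the time tested, camera with an estimated correlation, the hand-written list of intronless genes in place of the annotation, and each library left out in turn. Results without the small RNA entries were added after the data were seen.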

Results

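Sudemycin D6 (SD6) is a small molecule that modulates SF3B1, the subunit of the U2 small nuclear ribonucleoprotein (snRNP) that holds the branch point of an intron during splicing. Its effect on messenger RNA was followed in MEC1, a B-cell line from chronic lymphocytic leukaemia (CLL), and in GM12878, a lymphoblastoid B-cell line immortalised with Epstein-Barr virus. Cells were taken at 0 h and after 2, 6 and 24 h in 125 nM SD6, with 1 library for each line and time. The series title names intron retention and lower expression of B-cell receptor (BCR) pathway genes as its subjects. Estimated depth was 16.7 to 29.8 M fragments in GM12878 and 20.4 to 26.9 M in MEC1. The later times have no solvent control, so drug and time in culture were not separated, and no gene's change within a single line has a replicate check. In the deposited scaling the median change of all tested genes was -0.18 at 2 h, -0.48 at 6 h and -0.38 at 24 h on the log2 scale. Medians of gene lists are therefore also given relative to these values, and "after rescaling" means that each library was recentred to a median log ratio of 0.

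The size of the response addresses how fast and how widely SD6 changes expression in each line. At 2 h few genes had moved at least 2-fold, and the lower ones included TRAF1, an adaptor of tumour necrosis factor receptors, which went from 96.8 to 30 FPKM in GM12878 and from 56 to 18.9 FPKM in MEC1. By 6 h lower genes far outnumbered higher ones in both lines, and the same held at 24 h. In GM12878, of 10663 genes, 78 were higher and 151 lower at 2 h, 176 higher and 2037 lower at 6 h, and 498 higher and 2521 lower at 24 h. In MEC1, of 10707 genes, 93 were higher and 229 lower at 2 h, 200 and 2691 at 6 h, and 498 and 2736 at 24 h. After rescaling, the counts higher and lower at 6 h were 415 and 961 in GM12878 and 612 and 1051 in MEC1, and those at 24 h were 1182 and 1433 in GM12878 and 1175 and 1499 in MEC1. At 2 h rescaling gave 85 higher and 83 lower in GM12878 and 108 and 103 in MEC1. Most genes higher at 2 h were small RNAs, and without these, a choice made after the values were seen, 21 were higher in GM12878 and 33 in MEC1.

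Changes in the 2 lines were compared gene by gene. Across 10786 genes, which are not independent replicates, the changes of the 2 lines correlated with r = 0.72 at 2 h, 0.85 at 6 h and 0.79 at 24 h (Spearman's rho 0.69, 0.83 and 0.79). Genes at least 2-fold lower in both lines numbered 82 at 2 h, 1609 at 6 h and 1740 at 24 h, against 2.63, 492 and 617 for independent lists of these sizes. Those at least 2-fold higher in both numbered 13, 74 and 206, against 0.0575, 1.47 and 17.7. At least 2-fold in opposite directions were 0, 2 and 5 genes.

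**Figure D1:**
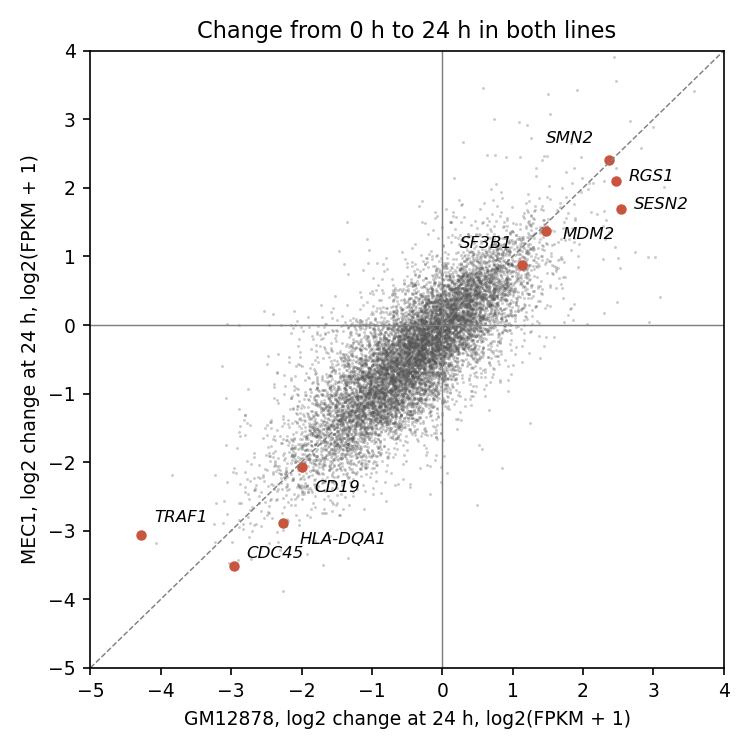
Log2 change from 0 h to 24 h in GM12878 (x axis) and MEC1 (y axis) on log2(FPKM + 1), 1 point per gene for 10775 genes (1 lies outside the axes and 139 small RNA entries were left out), with the line of equal change dashed. Named genes in red range from TRAF1 and CDC45 among the lower to SMN2 and RGS1 among the higher genes.

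Genes were ranked by their change at 24 h shared by both lines. TRAF1 fell by 3.67 ± 0.29 (SE; limma adjusted p = 0.000296). CD40, the receptor through which T cells activate B cells, changed by -3.00 ± 0.15 (adjusted p = 0.000233), from 82.9 to 8.68 FPKM in GM12878 and from 40.7 to 4.65 FPKM in MEC1. CDC45, part of the replicative helicase, and RRM2, a subunit of ribonucleotide reductase, changed by -3.24 and -3.00. Also among the 10 strongest decreases were RASSF4 (-3.63), a RAS-association protein, CENPM (-3.20), a centromere protein, FADS1 (-3.16), a fatty acid desaturase, ISG20 (-3.08), an interferon-induced exonuclease, MNF1 (-3.08), a mitochondrial protein, and UPK3BL (-3.25), whose near-identical copies make its value uncertain. SNORD12B also held a place by the rule, on 3 fragments or fewer per library, and lost its call without GM12878 24 h (adjusted p = 0.0667) or MEC1 0 h (0.0848). CD40 entered when small RNAs were left out.

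RGS1, a regulator of G protein signalling in B cells, rose by 2.29 ± 0.14 (limma adjusted p = 0.000241), from 62.8 to 352 FPKM in GM12878 and from 56 to 245 FPKM in MEC1. DDIT3, the stress transcription factor CHOP, rose by 2.08 ± 0.13 (adjusted p = 0.000241), MICB, a ligand of natural killer cell receptors, by 1.96, the adaptor GAB1 by 2.07 and the SUMO protease USPL1 by 2.20. ERMN (2.38), OVGP1 (2.67) and the noncoding LOC283624 (3.17) rose from low levels. SMN2 rose by 2.39 and the readthrough gene NME1-NME2 by 3.01, but reads of SMN2 can be shared with its copy SMN1 and those of NME1-NME2 with its 2 parts. These 10 genes were ranked after small RNAs were left out, a choice made after the values were seen. By the rule itself, the 10 places went to SNORD9, SNORA29, SNORA28, SCARNA1, SNORA42, SNORA72, SNORA6, SNORA68, SNORA3 and MIR941-3, most of them listed at 0 at 0 h in both lines. SNORA68 had the most fragments of those that could be read in whole fragments, 27 in GM12878 and 21 in MEC1 at 24 h. Without GM12878 0 h the calls of SNORD9 (adjusted p = 0.0791), SNORA28 (0.0775), SNORA42 (0.165) and MIR941-3 (0.127) were lost, and without MEC1 24 h those of SNORD9 (0.0629), SNORA28 (0.0633), SNORA42 (0.15) and SNORA72 (0.0731). SNORA72 also lost its call without GM12878 24 h (0.084) or MEC1 0 h (0.136), and MIR941-3 without GM12878 2 h (0.056), GM12878 24 h (0.269), MEC1 0 h (0.17) or MEC1 2 h (0.0562).

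In total 1457 genes rose and 4774 fell at 24 h of 10925 tested, and after rescaling 2769 rose and 3033 fell, so the share that rose went from 23.4% to 47.7%. The number that rose was 926 with only 0 h and 24 h fitted, 751 without the GM12878 0 h library and 821 without the MEC1 0 h library.

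Lists of genes written beforehand asked which pathways took part at 24 h. Targets of the tumour suppressor p53 moved up most: of 30, 17 rose and 0 fell (17 and 0 adjusted over the list alone, 23 and 0 after rescaling), with a median 1.27 above that of all genes. SESN2, which restrains mTORC1 under stress, rose by 2.12 ± 0.22 (limma adjusted p = 0.000631), the ubiquitin ligase and p53 inhibitor MDM2 by 1.42 ± 0.14 (adjusted p = 0.000517), and GADD45A, a growth arrest gene, by 1.98, a call lost without the GM12878 0 h library (adjusted p = 0.0505). CDKN1A, the cell cycle inhibitor p21, was not called (0.56, adjusted p = 0.253). Without the GM12878 24 h library its change was 1.32, a value that rests on the MEC1 24 h library alone. TP53 itself was not called (-0.02, adjusted p = 0.954) and went down in GM12878 and up in MEC1. Within single lines, 29 members were higher and 1 lower of 30 in GM12878, and 21 and 4 of 25 in MEC1. Resting on the MEC1 24 h library alone, the changes of the members DDB2 and TP53I3 were -0.57 and -0.56. That of TP53I3 was 0.55 without MEC1 24 h. The camera adjusted p of the list was 1.32e-10 (adjusted p = 0.719 with an estimated correlation), and its median lay at percentile 100 of random lists in both lines.

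Genes of antigen presentation and of B-cell identity moved down at 24 h. Of 14 MHC class II genes, 0 rose and 13 fell (14 adjusted over the list alone, 11 after rescaling), with a median 1.12 below that of all genes, written as -1.12 (camera adjusted p = 0.00156; adjusted p = 0.719 with an estimated correlation). HLA-DQA1, an antigen-presenting chain, fell by 2.58 ± 0.17 (limma adjusted p = 0.000245) and HLA-DOA fell by 2.60 ± 0.40 (adjusted p = 0.00231). The invariant chain CD74 fell by 0.76, a call lost after rescaling (-0.34, adjusted p = 0.0838), and reads of HLA genes can be shared between copies. Of 13 B cell markers 9 fell and 0 rose (9 and 0 adjusted over the list alone, 7 and 1 after rescaling). CD22, an inhibitory co-receptor, fell by 2.20 and CR2, a complement receptor, fell by 2.35. The camera adjusted p of the markers was 0.043 (0.719 with an estimated correlation), and 0.0924 without the GM12878 24 h library.

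Inflammatory and DNA repair lists also moved down. Of 28 NF-kappaB targets 17 fell and 0 rose (17 and 0 adjusted over the list alone, 13 and 1 after rescaling), with TRAF1 and CD40 the lowest members. The list's camera adjusted p was 0.0241 (0.719 with an estimated correlation), 0.062 without the GM12878 0 h library and 0.059 without the GM12878 24 h library. Of 32 homologous recombination and Fanconi genes 22 fell and 1 rose (23 and 1 adjusted over the list alone, 15 and 3 after rescaling), among them RBBP8, which starts end resection (-2.20), and FANCI (-1.98). Its camera adjusted p was 0.0235 (0.719 with an estimated correlation) and 0.0558 without the GM12878 24 h library.

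3 other lists lay above other genes while their members went both ways. In the order given below, their medians were -0.06, -0.00 and -0.06 in GM12878 and 0.13, 0.14 and 0.12 in MEC1. Of 40 SR and hnRNP splicing factors 13 rose and 12 fell (13 and 13 adjusted over the list alone, 22 and 6 after rescaling). Its median change was 0.14 and its mean -0.02 (camera adjusted p = 0.0228; 0.719 with an estimated correlation; 0.143 without the MEC1 24 h library). Of 25 integrated stress response genes 7 rose and 6 fell (7 and 6 adjusted over the list alone, 10 and 3 after rescaling), from DDIT3 down to the tryptophanyl-tRNA synthetase WARS (-1.47), with an adjusted p of 0.036 (0.719 with an estimated correlation; 0.159 without the MEC1 24 h library). Of 14 snoRNA host and decay-sensitive noncoding genes 4 rose and 2 fell (4 and 2 adjusted over the list alone, 8 and 0 after rescaling), led by ZNFX1-AS1 (1.37). This list's adjusted p was 0.0484 (0.719 with an estimated correlation), and it was no longer called without the GM12878 6 h (0.0502), MEC1 6 h (0.0503) or MEC1 24 h (0.236) library.

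**Figure D2:**
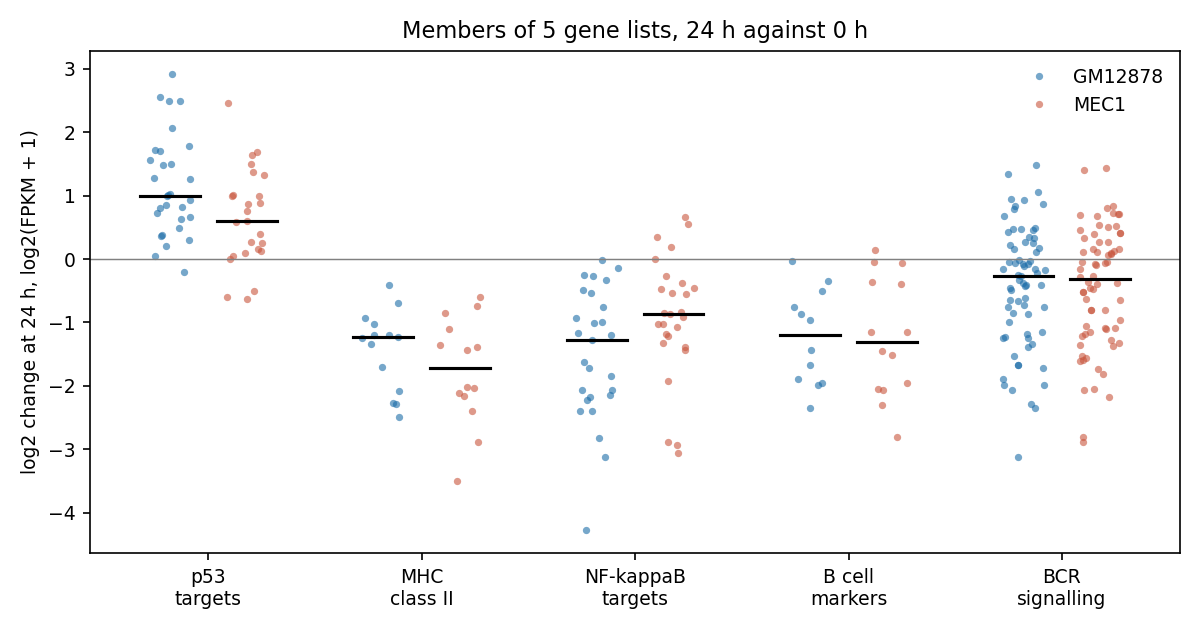
Log2 change at 24 h against 0 h on log2(FPKM + 1) for the members of 5 lists (x axis), 1 point per gene with a mean of at least 1 FPKM in that line, GM12878 in blue and MEC1 in red, with black bars for medians. Medians of p53 targets are 1.00 and 0.60 and those of MHC class II genes -1.24 and -1.72, while those of BCR signalling (-0.27 and -0.32) become 0.07 and 0.09 after rescaling.

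The other lists were not called at 24 h. Of 40 proliferation genes 12 rose and 18 fell (12 and 18 adjusted over the list alone, 17 and 16 after rescaling; adjusted p = 0.435): the cyclin CCNB2 (1.47) and the kinetochore protein CENPF (1.52) rose, whereas CDC45 and RRM2 fell. Of 35 interferon-stimulated genes 1 rose and 17 fell (0 and 17 adjusted over the list alone, 5 and 13 after rescaling; adjusted p = 0.2), with IFI35 (-2.75) and the antiviral GTPase MX1 (-2.08) lowest. Of 35 MYC targets 1 rose and 22 fell (1 and 22 adjusted over the list alone, 4 and 11 after rescaling), with the nucleotide synthesis enzyme CAD (-2.52) and the folate carrier SLC19A1 (-2.53) lowest. Its adjusted p of 0.0508 passed the threshold without the GM12878 2 h (0.0398), MEC1 0 h (0.0355), MEC1 2 h (0.0398) or MEC1 24 h (0.00101) library. MYC itself fell by 0.96, a call lost after rescaling (adjusted p = 0.128) and without the GM12878 0 h (0.129) or GM12878 24 h (0.0853) library. Of 78 cytosolic ribosomal proteins 1 rose and 11 fell (0 and 0 adjusted over the list alone), but 39 rose and 0 fell after rescaling. Its adjusted p of 0.133 became 3.54e-07 after rescaling, 0.0382 without the GM12878 0 h library and 0.0223 without the MEC1 24 h library. Members rose and fell as 4 and 10 among 27 immediate early genes (adjusted p = 0.67; DUSP2, a phosphatase, -2.06), 6 and 15 among 31 intronless genes (0.73), 0 and 6 among 26 replication-dependent histones (0.98), and 1 and 7 among 18 heat shock genes (0.98; 0.0429 without the MEC1 24 h library; BAG3, a co-chaperone, 1.25). They did so as 3 and 3 among 10 CLL markers (0.428; TCL1A, an AKT co-activator, -2.13, and FCER2, the IgE receptor CD23, -1.44), 1 and 11 among 16 housekeeping genes (0.325), and 2 and 4 among 10 plasma cell markers (0.98; PRDM1 1.11, MZB1 -2.56). After rescaling these counts were, in the same order, 8 and 5, 9 and 7, 0 and 3, 2 and 3, 4 and 2, 3 and 5, and 3 and 3. Counts adjusted over the list alone were 4 and 9 for immediate early genes, 0 and 4 for histones and 1 and 5 for heat shock genes, and for the others as given.

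Expression of the BCR pathway was the question set by the series title. Central members fell strongly at 24 h: the co-receptor CD19 fell by 2.03 ± 0.20 (limma adjusted p = 0.000508), from 35.4 to 8.14 FPKM in GM12878 and from 134 to 31.1 FPKM in MEC1. The kinase SYK, which starts signalling, fell by 1.78 ± 0.17 (adjusted p = 0.000467), the receptor chain CD79B fell by 1.42 ± 0.27 (adjusted p = 0.00479), and the kinase BTK, the target of ibrutinib, fell by 1.24 ± 0.13 (adjusted p = 0.000622). These 4 calls held after rescaling (-1.63, -1.43, -1.01 and -0.83). The other receptor chain, CD79A, stayed at 105 to 112 FPKM in GM12878 and 83.9 to 91.1 FPKM in MEC1. It was not called at 24 h (-0.05, adjusted p = 0.682) and was called up after rescaling (0.37, adjusted p = 0.0211). The SRC-family kinase LYN was not called either (0.10, adjusted p = 0.597) and was also called up after rescaling (0.51, adjusted p = 0.0202). PIK3CG, the gamma catalytic subunit of PI3 kinase, and its regulatory subunit PIK3R5 rose by 1.44 and 1.15.

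Several BCR genes were lower at 6 h than at 24 h. The adaptor BLNK fell by 1.89 ± 0.18 at 6 h (limma adjusted p = 0.000854), from 48 to 14.3 FPKM in GM12878 and from 78.7 to 17.7 FPKM in MEC1, and stood at 37.9 and 36.5 FPKM at 24 h. Its call at 24 h (-0.71, adjusted p = 0.0163) was lost after rescaling (-0.30, adjusted p = 0.199) and without the MEC1 0 h (0.132) or MEC1 24 h (0.0526) library. The scaffold CARD11 fell by 0.98 ± 0.13 at 6 h (adjusted p = 0.0018). Its call at 24 h (-0.38, adjusted p = 0.0446) was lost after rescaling (adjusted p = 0.982) and without any library other than MEC1 24 h (adjusted p 0.0704 to 0.214). The phospholipase PLCG2 fell by 0.71 at 24 h, a call lost after rescaling (-0.30, adjusted p = 0.0546). SYK and CD19 had already fallen at 6 h (-1.08 and -1.36), and held after rescaling.

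The list of 69 BCR genes was not called by camera at any time, except at 6 h with no filter (-0.33, adjusted p = 0.0156). At 6 h 1 rose and 38 fell (1 and 38 adjusted over the list alone, 7 and 19 after rescaling; camera adjusted p = 0.189; 0.707 with an estimated correlation), with a median of -0.11 relative to all genes. At 24 h 12 rose and 31 fell (12 and 31 adjusted over the list alone, 26 and 20 after rescaling; adjusted p = 0.792; 0.973 with an estimated correlation), with a relative median of 0.02. At 2 h 0 rose and 0 fell (adjusted p = 0.529; 0.866 with an estimated correlation). The list median stood at percentiles 0.585, 1.16 and 84.5 of random lists in GM12878 and 3.18, 17.9 and 72.4 in MEC1 at 2, 6 and 24 h. In GM12878 the medians at 2 h (-0.20) and 6 h (-0.55) lay below the range of random lists (from -0.18 and -0.52).

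**Figure D3:**
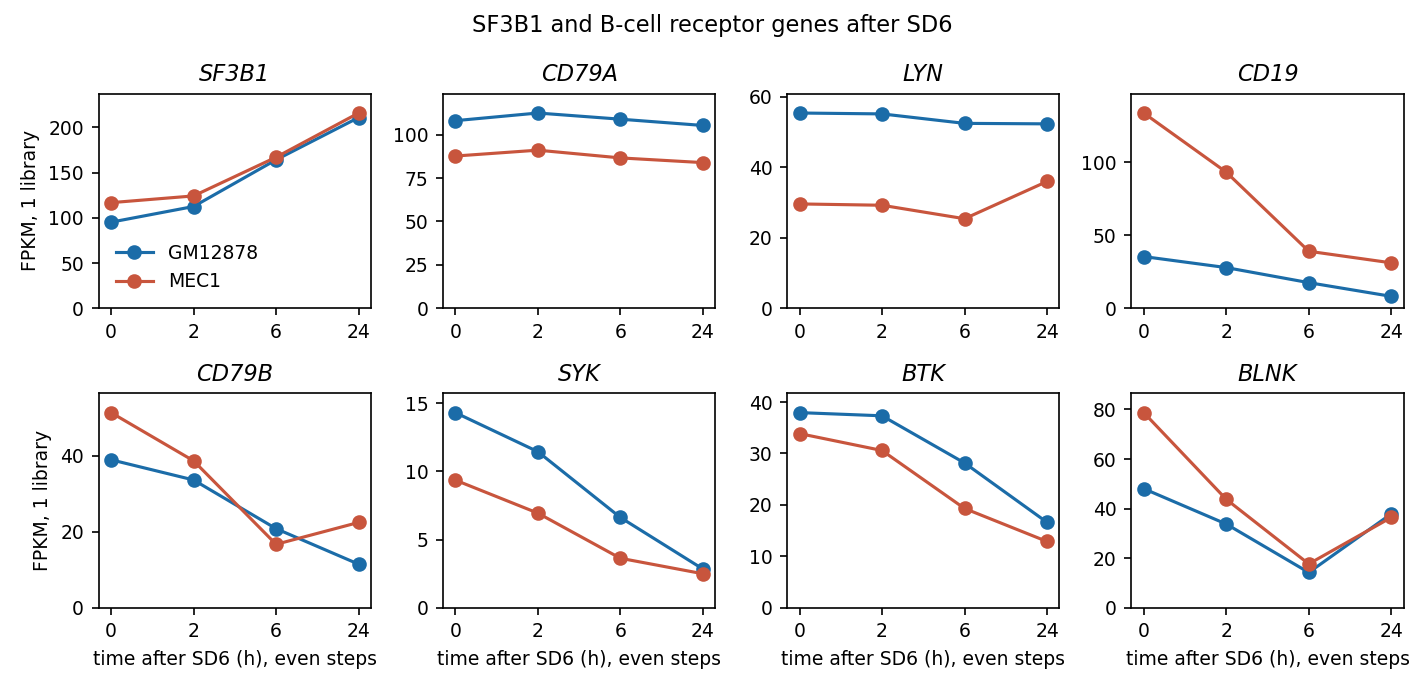
FPKM (y axis) of SF3B1 and 7 BCR genes at 0, 2, 6 and 24 h of SD6 (x axis, evenly spaced), 1 library per point, GM12878 in blue and MEC1 in red. CD19, SYK and BTK are lower at each later time in both lines, CD79A stays between 83.9 and 112 FPKM (and was called up after rescaling), and BLNK is lowest at 6 h.

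The drug target and its partners were examined next. SF3B1 rose by 0.65 ± 0.11 at 6 h (limma adjusted p = 0.00408) and by 1.01 ± 0.11 at 24 h (adjusted p = 0.000699), from 95.1 to 211 FPKM in GM12878 and from 117 to 216 FPKM in MEC1. SMNDC1, a factor of spliceosome assembly, rose by 0.96, and U2SURP, a U2-associated protein, fell by 0.85. SF1, which binds the branch point before the U2 snRNP, fell by 0.73, a call lost after rescaling (adjusted p = 0.0808). Of 24 SF3b and U2 snRNP genes 6 rose and 6 fell at 24 h (6 and 6 adjusted over the list alone, 11 and 1 after rescaling; camera adjusted p = 0.0775, after rescaling 0.0108). Among other splicing factors, PTBP2, a paralogue of the repressor PTBP1, rose by 1.29 ± 0.13 (adjusted p = 0.000606) and the coactivator SRRM1 by 1.16. HNRNPU fell by 1.44, and SRSF7 fell by 1.49, a call lost without the GM12878 0 h library (adjusted p = 0.0549).

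Regulators of apoptosis set how B cells respond to BCL2 inhibitors. BCL2 itself, the target of venetoclax, rose by 1.09 ± 0.13 (limma adjusted p = 0.000831), from 22.2 to 52.7 FPKM in GM12878 and from 21.1 to 42.3 FPKM in MEC1. The death-promoting genes BBC3 and PMAIP1, both p53 targets, rose by 1.71 and 1.25, while BAD fell by 1.46. The protective BCL2A1 fell by 1.32. BCL2L1, which encodes BCL-XL, fell by 0.80, a call lost after rescaling (-0.41, adjusted p = 0.126) and without the GM12878 0 h library (0.0727). MCL1 rose by 0.36 (adjusted p = 0.0371), a call lost without the GM12878 0 h (0.145), GM12878 2 h (0.0961), MEC1 0 h (0.182), MEC1 2 h (0.0958) or MEC1 24 h (0.0729) library. Of 15 BCL2 family genes 5 rose and 6 fell at 24 h (5 and 6 adjusted over the list alone, 6 and 3 after rescaling; camera adjusted p = 0.41).

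The same ranking at 6 h again had TRAF1 and CD40 among the strongest decreases. TRAF1 (-3.91 ± 0.29), CD40 (-2.81 ± 0.15), DYNLT1, a dynein light chain (-3.38 ± 0.23), SLC25A19, the mitochondrial thiamine pyrophosphate carrier (-3.13 ± 0.25), and JAGN1, a protein of the endoplasmic reticulum (-3.16 ± 0.24), each had a limma adjusted p of 0.000669. UNC50 (-2.92), RRP8 (-2.81), PYGO2 (-2.74), ZFPL1 (-2.64) and NR2C2AP (-2.59) followed, the last entering when small RNAs were left out and SNORA7A holding its place by the rule, though its call was lost without GM12878 0 h (0.125), GM12878 6 h (0.091), MEC1 0 h (0.0987) or MEC1 6 h (0.186). Several recovered in part by 24 h: RRP8, which methylates ribosomal RNA, went from 14.9 to 1.28 and then 10.3 FPKM in GM12878. The strongest increases outside small RNAs, chosen after the values were seen, were mostly noncoding: LOC90834 (2.49), LOC283888 (2.23), AKIRIN2-AS1 (2.11), LOC100130855 (2.11), LOC283624 (2.04), LOC100288123 (2.01) and C8orf39 (1.91), with OVGP1 (2.78), ERMN (2.08) and TAF1D (1.79), a host of small nucleolar RNAs. Some small RNAs placed by the rule rested on very few fragments at 6 h. SNORD11B had 1 in each line and 0 at other times, and SNORA38 had 5 in GM12878 and 2 in MEC1. By the rule itself the places went to SNORD9, SNORA29, SNORD11B, SNORA72, SNORA6, SNORA38, SNORA54, SNORA3, SCARNA1 and SNORA23. Of these, SNORD9 and SNORA54 lost their calls without GM12878 0 h (0.0819 and 0.178) or MEC1 6 h (0.119 and 0.229), and SNORA72 without GM12878 6 h (0.0555).

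In total 590 genes rose and 5275 fell at 6 h, and 1888 rose and 2543 fell after rescaling, so the share that rose went from 10.1% to 42.6%. With a minimum mean of 5 FPKM 3477 fell. The number that rose was 251 without the MEC1 0 h library, 269 without MEC1 6 h, 285 without GM12878 6 h, 309 without GM12878 0 h and 888 without either 24 h library. The number that fell was 2974 without MEC1 0 h and 3125 without MEC1 6 h.

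6 lists stood above other genes at 6 h. The 78 ribosomal protein genes, which are short, highly expressed and long-lived transcripts, moved up by 0.68 relative to all genes, with 23 rising and 0 falling (0 and 0 adjusted over the list alone, 74 and 0 after rescaling; camera adjusted p = 5.22e-28; 0.707 with an estimated correlation). SR and hnRNP splicing factors had 12 rising and 7 falling (11 and 6 adjusted over the list alone, 25 and 3 after rescaling; adjusted p = 4.3e-06; 0.707). Histones, whose messages have no introns, had 2 and 2 (1 and 0 adjusted over the list alone, 8 and 0 after rescaling; 0.000291; 0.707), and intronless genes 3 and 3 (9 and 0 after rescaling; 0.002; 0.707). SnoRNA hosts had 4 and 2 (9 and 2 after rescaling; 0.00453; 0.707). The p53 targets had 1 rising and 8 falling (1 and 4 adjusted over the list alone, 6 and 1 after rescaling), so members fell while the list lay 0.21 above all genes. Their adjusted p of 0.0332 (0.874 with an estimated correlation) was lost after rescaling (0.18) and without the GM12878 0 h (0.153) or GM12878 6 h (0.13) library.

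Other lists were not called at 6 h. Genes rose and fell as 0 and 22 for homologous recombination (adjusted p = 0.189), 0 and 17 for interferon-stimulated genes (0.568), 0 and 16 for NF-kappaB targets (0.657), 2 and 16 for proliferation genes (0.282; 0.0477 without MEC1 6 h), 0 and 13 for MYC targets (0.772), and 0 and 4 for MHC class II (0.736). SF3b and U2 snRNP genes had 3 rising and 7 falling (0.0786; 9 and 1 after rescaling, 0.00562; 0.0375 without MEC1 6 h), and the BCL2 family 1 and 8 (0.999; 1 and 10 adjusted over the list alone). Immediate early genes had 1 and 13 (0.999), integrated stress response genes 2 and 13 (0.999), heat shock genes 0 and 7 (0.999), CLL markers 1 and 3 (0.295), housekeeping genes 1 and 6 (0.381), B cell markers 0 and 6 (0.381) and plasma cell markers 1 and 3 (0.709). Adjusted over the list alone, 16 interferon-stimulated genes, 15 proliferation genes, 12 MYC targets and 3 MHC class II genes fell, and the other counts in this paragraph were the same. Most of these falls depended on the scaling: after rescaling 3 rose and 8 fell for homologous recombination, 0 and 7 for interferon-stimulated genes, 3 and 8 for NF-kappaB targets, 13 and 6 for proliferation genes, 7 and 6 for MYC targets and 3 and 1 for MHC class II. The counts were then 3 and 2 for the BCL2 family, 3 and 4 for immediate early genes, 2 and 1 for integrated stress response genes, 2 and 3 for heat shock genes, 1 and 0 for CLL markers, 8 and 4 for housekeeping genes, 1 and 5 for B cell markers and 1 and 2 for plasma cell markers.

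At 2 h the ranking rested on fewer calls. PCF11, which ends transcripts at the poly(A) site, fell by 1.41 (limma adjusted p = 0.0331), from 13.4 to 4.43 FPKM in GM12878 and from 14.4 to 4.79 FPKM in MEC1, and had risen by 1.37 at 24 h. POLR3D, a subunit of RNA polymerase III, changed by -1.47, RRP8 by -1.69, JAGN1 by -1.61 and NR2C2AP by -1.47. LOC283888 (1.82), AKIRIN2-AS1 (1.63), LOC90834 (1.58), LOC100130855 (1.47) and C8orf39 (1.34), chosen after the values were seen, rose. By the rule itself the places went to SNORA29, SNORA6, SNORA71D, SCARNA1 and SNORA3. The calls of the 10 genes other than small RNAs were lost without GM12878 0 h (adjusted p 0.124 to 0.253), GM12878 2 h (0.171 to 0.266), GM12878 6 h (0.117 to 0.126), MEC1 0 h (0.211 to 0.314), MEC1 2 h (0.308 to 0.385) or MEC1 6 h (0.119 to 0.129), and those of SNORA6, SNORA71D, SCARNA1 and SNORA3 without at least 1 of these (0.0509 to 0.344). After rescaling the calls of PCF11 (0.0517), POLR3D (0.0647), RRP8 (0.0647), JAGN1 (0.08), LOC283888 (0.0552), AKIRIN2-AS1 (0.0651), LOC100130855 (0.0651) and SNORA3 (0.072) were lost, and with no filter all 15 calls were lost. SNORA29 alone among the 15 stayed called in every fit that left out 1 library. It was listed at 0 at 0 h in both lines and had 6, 17 and 6 fragments in GM12878 and 7, 11 and 6 in MEC1 at 2, 6 and 24 h.

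39 genes rose and 144 fell at 2 h (29 and 337 without small RNAs), with 2475 at an unadjusted p under 0.05, and 21 rose and 5 fell after rescaling, so the share that rose went from 21.3% to 80.8%. With only 0 h and 2 h fitted 223 rose and 3232 fell, with no filter 0 and 0, and with a minimum mean of 5 FPKM 16 and 13. The number that fell was 85 with a pseudocount of 5 and 239 without the intensity trend. The calls rested on single libraries. Without the GM12878 2 h library 2 rose and 0 fell, without GM12878 0 h 7 and 4, without GM12878 6 h 3 and 0, without MEC1 0 h 7 and 1, without MEC1 2 h 6 and 0, and without MEC1 6 h 3 and 0. Without the GM12878 24 h library 96 rose and 1284 fell, and without MEC1 24 h 96 and 1311.

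Ribosomal proteins lay above other genes at 2 h with 0 rising and 0 falling (camera adjusted p = 1.54e-13; 0.709 with an estimated correlation), as did SR and hnRNP splicing factors with 1 and 0 (1 and 1 adjusted over the list alone; 1.66e-05; 0.709) and snoRNA hosts with 1 and 0 (3 and 1 adjusted over the list alone; 0.00195; 0.709). The call of the histones (0.00182; 0.709) was lost after rescaling (0.0958) and without MEC1 0 h (0.398). That of the intronless genes (0.023; 0.866 with an estimated correlation) was lost after rescaling (0.0958) and without GM12878 2 h (0.43), GM12878 24 h (0.0557), MEC1 0 h (0.287) or MEC1 24 h (0.0547). SF3b and U2 snRNP genes were not called (0.055) but were after rescaling (0.00244) and without GM12878 24 h (0.0498) or MEC1 24 h (0.0492). The remaining lists had adjusted p of 0.248 to 0.989, except that NF-kappaB targets were called without MEC1 0 h (0.00271) and p53 targets without MEC1 2 h (0.0229), both down.

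Intron content addresses intron retention indirectly, since gene-level FPKM cannot show retained introns. Protein-coding genes without introns kept higher values than spliced genes at 2 h and 6 h in both lines. At 6 h the median change of 173 intronless genes in GM12878 was 0.16, against -0.47 for genes with introns, and that of 187 in MEC1 was 0.14, against -0.57. Both lay at percentile 100 of matched random lists. At 6 h genes lost more the more introns they had: medians were -0.35, -0.45 and -0.57 in GM12878 and -0.37, -0.56 and -0.70 in MEC1 for 1 to 4, 5 to 9 and 10 or more introns. After rescaling the order was kept (0.47, 0.01, -0.09 and -0.20 from none to 10 or more in GM12878, and 0.61, 0.11, -0.07 and -0.22 in MEC1), and genes with 1 to 4 introns changed sign. The order did not hold in GM12878 at 2 h (-0.18, -0.17 and -0.16) or 24 h (-0.40, -0.40 and -0.39), while in MEC1 it was -0.18, -0.21 and -0.25 at 2 h and -0.37, -0.39 and -0.48 at 24 h. At 2 h the medians of genes without and with introns were -0.01 and -0.17 in GM12878 and -0.03 and -0.22 in MEC1, also at percentile 100. At 24 h they were closer, -0.27 and -0.39 in GM12878 (percentile 94.5) and -0.25 and -0.42 in MEC1 (percentile 98.9), and the hand-written list of intronless genes lay below genes with introns in GM12878 (a difference of -0.25). Rescaling made the intronless medians positive at 2 h (0.14 in both lines) and at 24 h (0.06 and 0.13).

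**Figure D4:**
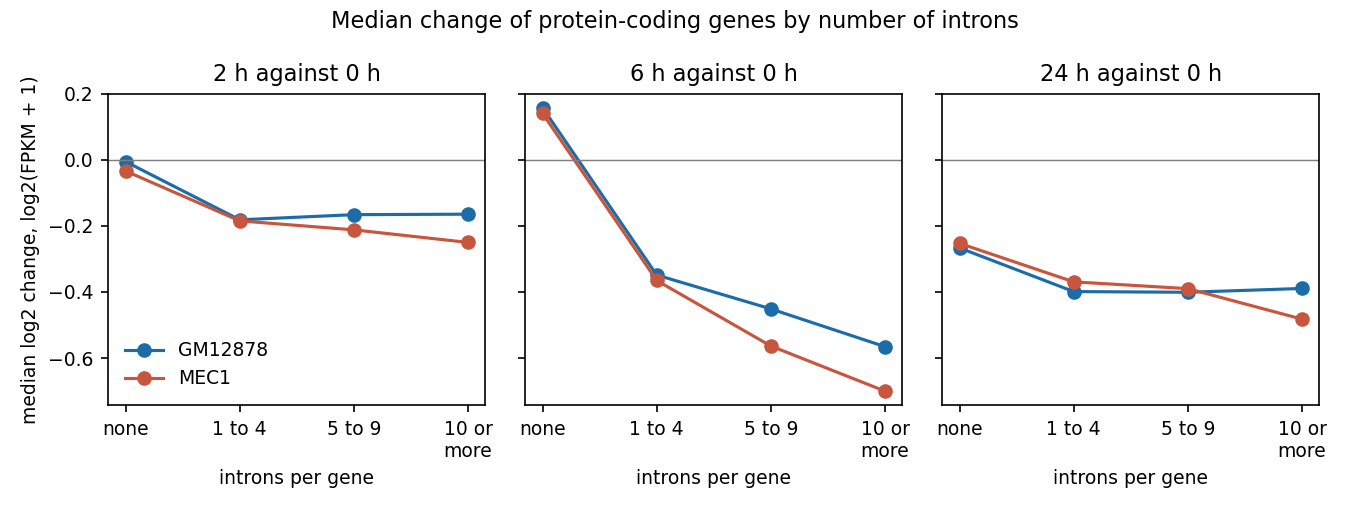
Median log2 change on log2(FPKM + 1) (y axis) of protein-coding genes with no, 1 to 4, 5 to 9 and 10 or more introns (x axis) at 2, 6 and 24 h against 0 h, GM12878 in blue and MEC1 in red. At 6 h the medians go from 0.16 and 0.14 without introns to -0.57 and -0.70 with 10 or more; after rescaling the intronless medians at 2 h and 24 h and those of 1 to 4 introns at 6 h become positive.

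The difference between the lines compares a leukaemia line with an immortalised B-cell line over all 4 times. MEC1 had more BCHE, which encodes butyrylcholinesterase (5.65 ± 0.16; limma adjusted p = 1.02e-05), GNLY, the cytotoxic protein granulysin (5.19 ± 0.14; 9.96e-06), BANK1, a B-cell scaffold (4.61), the cytokine LTB (4.28) and T, the transcription factor brachyury (4.14). GM12878 had more PLS3, an actin bundler (-5.55 ± 0.10; 4.29e-06), LAMP3 (-5.25), the ubiquitin-like UBD (-5.18, with changes at 24 h of opposite sign in the lines), GUCY1B3 (-4.79), the interleukin receptor IL1R1 (-4.61) and PALLD (-4.53). HLA-DRB5 was higher in MEC1 by 5.28, but its reads can be shared with other HLA genes. The small RNAs SNORA41 and SNORA43 in MEC1 and SNORD12B and SNORA37 in GM12878 completed the rule's places on few fragments. The calls of SNORA43 and SNORD12B were lost without GM12878 6 h (adjusted p 0.0697 and 0.192) or MEC1 6 h (0.0702 and 0.192), and that of SNORD12B also without GM12878 2 h (0.143) or MEC1 2 h (0.143). In total 3183 genes were higher in MEC1 and 2814 in GM12878, and 3120 and 2932 after rescaling. The 4 libraries of a line are 1 time course each, not independent cultures.

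Among lists, p53 targets were lower in MEC1 (0 higher, 23 lower; 1 and 23 adjusted over the list alone; camera adjusted p = 6.56e-07; 0.642 with an estimated correlation), and TP53 itself was lower by a log2 difference of -2.19. Interferon-stimulated genes were lower in MEC1 as well (3 higher, 28 lower; 4 and 28 adjusted over the list alone; 6.56e-07; 0.642), as were CLL markers (1 and 6; 1 and 8 adjusted over the list alone; 0.00784; 0.642). Ribosomal proteins (51 and 3; 52 and 4 adjusted over the list alone; 6.56e-07; 0.642), snoRNA hosts (11 and 0; 12 and 0 adjusted over the list alone; 0.000202; 0.642), MHC class II (11 and 0; 13 and 0 adjusted over the list alone; 0.000476; 0.642) and MYC targets (19 and 4; 21 and 4 adjusted over the list alone; 0.0113; 0.794) were higher in MEC1. NF-kappaB targets were lower in MEC1 (5 and 12; 0.0297; 0.791), which was lost without GM12878 0 h (0.112) or MEC1 0 h (0.111). Proliferation genes were higher (14 and 2; 12 and 1 adjusted over the list alone; 0.041; 0.868), which was lost without GM12878 0 h (0.0579), MEC1 0 h (0.0566), GM12878 24 h (0.161) or MEC1 24 h (0.163). The other 13 lists were not called between the lines (adjusted p 0.148 to 0.999), BCR signalling among them with 21 genes higher and 17 lower in MEC1 (0.899).

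Responses in 1 line only were not tested, since each line has 1 library per time. PIDD, a p53-induced death domain gene, went from 12.1 to 35.2 FPKM at 24 h in GM12878 and from 12.5 to 11 FPKM in MEC1. MFSD2A, a lipid transporter, went from 5.89 to 0.607 FPKM in GM12878 and from 7.56 to 8.9 FPKM in MEC1. In MEC1 the transcription factor ZBED6 went from 5.88 to 29.5 FPKM, against 5.04 to 5.76 FPKM in GM12878, and the interferon-induced IFI44L from 21.7 to 3.62 FPKM, against 27.5 to 27.2 FPKM. These genes were chosen after the values were seen, because the rule gave small RNAs on few fragments.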

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

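Among the tests in this part, those of scaling and depth for the genes lower at 6 h, and those of depth, short RNA retention, retained introns, weighted host changes and TAF1D for the small RNAs, were chosen only after the result was seen.

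3 named genes went opposite ways in the 2 lines at every time after SD6. TP53, the tumour suppressor gene, had 36.6, 32.6, 25.7 and 21.9 FPKM at 0, 2, 6 and 24 h in GM12878 and 4.56, 4.65, 5.49 and 7.82 FPKM in MEC1, a difference in log2 change at 24 h of 1.38. UBD, a ubiquitin-like protein induced by cytokines, had 75.5, 66, 65.3 and 41.8 FPKM in GM12878 and 0.309, 0.403, 0.875 and 1.42 FPKM in MEC1 (a difference of 1.73), and the histone gene HIST1H2BJ had 7.45, 7.31, 5.33 and 5.45 FPKM in GM12878 and 0.385, 1, 1.02 and 2.15 FPKM in MEC1 (a difference of 1.58). These differences were not tested, because each line has 1 library per time, and no technical or biological explanation was tested for them. They were found among 190 named genes and 22 lists compared between the lines.

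In 8 groups of 4 libraries of a line, the library at 1 end stood apart from the other 3 by most of the group's range. HLA-DRB5, an antigen-presenting chain, was 77.9 FPKM in MEC1 at 24 h against 167 to 168 FPKM before (gap 0.989 of the range). GNLY was detected in GM12878 at 24 h alone, at 0.0584 FPKM (gap 1), and LAMP3 in MEC1 at 2 h alone, at 0.0429 FPKM (gap 1). The small RNAs SNORA41 in GM12878 (gap 1), SNORD12B in GM12878 (0.841) and MEC1 (1) and SNORA37 in MEC1 (1) rested on 3 fragments or fewer in each library. The relative depth of MEC1 at 0 h was above that of the later MEC1 libraries (gap 0.927). Libraries of 1 line differ in time, so a gap can be part of the time course, and of the 44 groups tested chance alone gives about 1 in 20.

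A widespread pattern in the deposited scaling was the lower level of spliced genes at 6 h, as in BLNK and DYNLT1, relative to intronless genes. How far levels fell stays open, since after rescaling the medians were 0.47 in GM12878 and 0.61 in MEC1 without introns, 0.0093 and 0.11 with 1 to 4, and -0.20 and -0.22 with 10 or more, and only the difference between these groups is free of the scaling. Depth rose from 0 h to 6 h in GM12878 (ratio 1.20) and dropped in MEC1 (0.757), while both medians were lower, and against random lists of the same transcript lengths intronless genes still stood at least 0.615 higher (percentile 100 in both lines). Within bins of length and mean level, genes with 10 or more introns had changed by -0.26 in GM12878 and -0.39 in MEC1 relative to genes with 1 to 4 introns, where the middle 95% of shuffled intron numbers was -0.05 to 0.04 and -0.06 to 0.04. A loss of spliced transcripts that grows with the number of introns after SD6 may explain the difference between these groups. The bins matched only transcript length and mean level, so other traits that may go with intron number, such as gene span, were not tested. Without a solvent control an effect of time in culture was not tested either, and both stay open.

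Small RNAs that lie inside other genes, such as SNORA29 and SNORA68, gained fragments soon after SD6: 98 of them together went from 185 per library to 422 at 2 h, 473 at 6 h and 386 at 24 h in GM12878 and from 312 to 622, 605 and 391 in MEC1. Relative to depth this was at least 2.02 times as many at 2 h and 6 h (95% interval from 1.69 for that lowest ratio), which argues against depth, but 1.17 times (0.979 to 1.40) in GM12878 and 1.62 times (1.39 to 1.88) in MEC1 at 24 h. More short RNA kept in the libraries would also raise small RNAs outside other genes, but only 2 of these could be read in fragments, with 28 over all libraries and 0 at 0 h in GM12878; in MEC1 they had 0.722 times as many at 2 h and 6 h (0.278 to 1.90) against 2.58 (2.28 to 2.93) inside, which goes against it on 2 small RNAs in 1 line, so it stays open, as do fragments of retained introns, since the 82 inside introns rose at least 1.95 times and only reads across the introns can tell these apart. The host genes had median changes at 6 h of -0.0354 in GM12878 and -0.13 in MEC1, and weighted by fragments their changes would give 1.36 and 1.38 times as many small RNA fragments, against 2.46 and 2.81 found for the 88 with a host value (intervals from 2.04 and 2.40), which argues against more host transcripts as the whole cause. TAF1D was the host with the most fragments of small RNAs (22 to 94 in GM12878 and 23 to 95 in MEC1 at 6 h). For these small RNAs, the log2 rise of the host by 1.70 and 1.87 at 6 h (3.26 and 3.66 times) could be the cause. This stays open because at 2 h in MEC1 the small RNAs gained 4.76 times (from 2.97) and the host 2.42 times.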

How the results depend on the processing

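The results without small RNAs were chosen only after the result was seen, and the other alternatives before. The calls of TRAF1, CD40, CD19, SYK, SESN2, MDM2, BCL2 and SF3B1 at 24 h kept their direction and their side of the threshold in every fit run. Of 182 called and 47 uncalled results of named genes, each a gene at 1 time or between the lines, rescaling ended 24 calls, added 11 of the same sign and called CD79A, uncalled before, with the other sign. It became 0.37 at 24 h (adjusted p = 0.0211; -0.05 before) and 0.48 at 6 h (0.0115; -0.00 before), since rescaling adds nearly the same amount to every gene of a library. Leaving out 1 library ended 175 calls and added 27 in 1832 fits, and called TP53I3, a p53 target uncalled at 24 h (-0.01, adjusted p = 0.987), with the other sign without MEC1 24 h (0.55, adjusted p = 0.0275; -0.56 without GM12878 24 h). For named genes no filter ended 26 calls and added 1, a minimum mean of 5 FPKM ended 7 and added 1, and fits of only 0 h and the time tested ended 7 and added 9. Among lists, all 28 calls of 85 ended with an estimated correlation. Rescaling ended 3 and added 4, no filter ended 6 and added 4, a minimum mean of 5 FPKM ended 6 of 26, and leaving out 1 library ended 22 and added 13 in 680 fits.

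Rescaling moved the numbers of genes changed at least 2-fold. In GM12878 83 were lower at 2 h, 415 higher and 961 lower at 6 h, and 1182 and 1433 at 24 h. In MEC1 these were 103, 612 and 1051, and 1175 and 1499. The shared calls became 21 up and 5 down at 2 h, 1888 and 2543 at 6 h, and 2769 and 3033 at 24 h. The cause is the shift of all values of a library.

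A larger pseudocount shrinks the changes of low genes. With a pseudocount of 5, GM12878 had 17 lower at 2 h, 81 higher and 553 lower at 6 h, and 214 and 1198 at 24 h, MEC1 had 39, then 95 and 888, and 218 and 1267, and 85 shared calls were down at 2 h. With a pseudocount of 0.1, 388 in GM12878 and 528 in MEC1 were lower at 2 h. A minimum mean of 5 FPKM tests fewer genes: 61 were lower at 2 h, 1217 lower at 6 h and 325 higher at 24 h in GM12878, and 92 lower at 2 h and 1673 lower at 6 h in MEC1. The shared calls were then 16 up and 13 down at 2 h and 3477 down at 6 h. With no filter, 0 genes were up and 0 down at 2 h, and the BCR signalling list at 6 h passed the threshold (-0.33 relative to all genes, adjusted p = 0.0156). Without small RNAs 21 genes were higher at 2 h in GM12878 and 33 in MEC1, and 337 shared calls were down at 2 h. The cause was not tested.

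Without the intensity trend 239 genes were down at 2 h. With only 0 h and the time tested, 223 were up and 3232 down at 2 h, and 926 were up at 24 h. The cause was not tested. The hand-written list of intronless genes stood above genes with introns by 0.50 in GM12878 and 0.50 in MEC1 at 6 h, and below them in GM12878 at 24 h (-0.25, reversed), with other genes in the list.

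With 1 library left out, which assumes that a time with 1 library left varies like the others, genes up were 2 to 96 at 2 h, 251 to 888 at 6 h and 751 to 1649 at 24 h, and genes down 0 to 1311, 2974 to 6298 and 3226 to 4934. Genes higher in MEC1 were 2247 to 3501, and in GM12878 2113 to 3060. The BCR list stayed uncalled at -0.07 to -0.00235 at 2 h (adjusted p 0.388 to 0.555), -0.12 to -0.07 at 6 h (0.148 to 0.246) and -0.01 to 0.04 at 24 h (0.776 to 0.88). The count test was not run because the file holds no counts. Depth limits mainly the small RNAs: those named that could be read in whole fragments had at most 27 per library.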

Other observations

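The tests of the cell cycle sets were chosen before their result was seen, and the sets of lipid, proteasome, mitochondrial and zinc finger genes were chosen only after the result was seen.

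The proliferation genes went apart at 24 h by the phase of the cell cycle they serve. Of the fixed list, 17 of 17 S phase genes fell, among them CDC45 and RRM2, while of 23 mitotic genes 12 rose and 1 fell, with CENPF and CCNB2 highest. After rescaling 15 S phase genes fell, and 17 mitotic genes rose and 1 fell. In genes outside the fixed lists, 29 of 31 S phase genes fell and 1 rose (25 and 2 after rescaling), with medians of -1.51 in GM12878 and -1.17 in MEC1, and of 36 mitotic genes 11 rose and 5 fell (24 and 4 after rescaling), with medians of 0.22 and 0.38. The median of mitotic genes lay above that of S phase genes by 1.74 in GM12878 and 1.55 in MEC1. The middle 95% of random pairs of lists reached 0.501 at most when matched on intron number, and 0.553 when matched on mean level, which a scaling factor would move alike, so these are argued against as the whole cause. A larger share of cells in G2 or mitosis at 24 h is a candidate explanation, as a hypothesis, since no cell cycle measurement was available and the drug was not separated from time in culture.

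Lipid, proteasome, mitochondrial and zinc finger genes were set against random lists at 24 h. Of 24 sterol and fatty acid genes 22 fell and 0 rose (19 and 1 after rescaling), with medians of -1.74 in GM12878 and -1.40 in MEC1, both at percentile 0 of random lists. Of 38 proteasome genes 27 fell (21 fell and 4 rose after rescaling), of 77 mitochondrial ribosomal proteins 61 fell and 3 rose (39 and 5 after rescaling), and of 43 NADH dehydrogenase genes 28 fell and 0 rose (18 and 6 after rescaling). Their medians lay at percentiles 0.11, 0.02 and 6.32 in GM12878 and 0.05, 0.62 and 0.05 in MEC1, so NADH dehydrogenase genes in GM12878 (-0.68) were inside the range of random lists (-0.74 to -0.14). Zinc finger genes went the other way, with 123 of 349 rising and 51 falling (182 and 19 after rescaling), and medians of 0.26 and 0.19 at percentile 100.

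Genes that mark other cell types were mostly low. A mean of at least 1 FPKM was reached by 3 of 17 T and NK cell markers (GNLY, PRF1 and LCK), 1 of 15 monocyte and neutrophil markers (ITGAM), 0 of 15 erythroid and platelet markers and 3 of 14 fibroblast and epithelial markers (ACTA2, CDH1 and COL1A1). ACTA2 rose at 24 h, and COL1A1 fell by 1.05, a call lost without GM12878 0 h (adjusted p = 0.067). None of 13 mitochondrially encoded genes was in the table. Small RNAs took 4.21% of the FPKM sum at 0 h in GM12878 and 7.39%, 9.09% and 9.78% at 2, 6 and 24 h, and 6.14%, 8.99%, 9.57% and 6.30% in MEC1. These are shares of FPKM and not of fragments, since FPKM divides by transcript length. SNORD9, for example, had 918 FPKM in GM12878 at 2 h on 1 fragment.

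The difference between the lines was set against other splits of the 8 libraries into 4 and 4. Of 35 splits 3 could not be fitted, and of the other 32 only 1, the real one, gave as many as its 5997 genes, the highest other giving 2. This argues against a chance division of the libraries only in that they divide by line. The other splits mix the lines and carry their difference as residual spread, so they could call few genes whatever its cause. The 4 libraries of a line are 1 time course, so a difference of this size between 2 cultures of the same line was not tested.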
